A study of Homo sapiens with 4 samples.

How the data were processed

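Gene expression was measured with Affymetrix arrays of 22283 probe sets in 4 established cell lines, 1 array each. Per the labels, SK-N-MC is an Ewing family tumor line, and SIMA, CHP-126 and SH-SY5Y are neuroblastoma lines. Per the labels, total RNA was extracted with Trizol and biotinylated cRNA was prepared from 10 ug by the standard Affymetrix protocol. The deposited values are signal intensities on a linear scale, 1 per probe set and array, per the labels and the values themselves. The software and the background method behind these intensities are not given in the sources used here. The mean signal after trimming 2% of the probe sets at each end was 500.2 on each array, so the values were used as deposited, with no further scaling.

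Values were taken as log2(signal + 50), the pseudocount being 0.1 of the common trimmed mean. A signal under 100, which is 0.2 of that mean, was treated as dim. Probe sets that were dim on all 4 arrays were left out, as were 68 control probe sets, Y-linked genes and XIST. Before this filter, and without the controls, 19065 probe sets carried 1 gene symbol, 1043 carried several and 2107 had none listed, and only those with 1 symbol were used for genes. Symbols were brought up to date through Entrez identifiers for 19053 of them. Each gene was represented by its probe set with the highest mean log2 value, which gave 9426 genes of 11939. No genome build was given for the arrays, so gene order and chromosome were taken from the GRCh38.p14 annotation and no coordinates are given. NR0B1, chosen as a gene to name, had no probe set with a single symbol and is not reported.

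SK-N-MC was compared with the 3 neuroblastoma lines by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes and two-sided tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All 2 residual degrees of freedom came from the neuroblastoma lines, and the prior added 3.32. Of the called genes lying on the same side of all 3 neuroblastoma lines and with the higher group at a mean signal of at least 250, the 12 with the highest and the 12 with the lowest difference were named. Up to 4 members of each list with the largest absolute difference were also selected, as was a fixed set of anchor genes. Not all of these are printed, and EGFR, HOXB7 and the anchors EWSR1, CCND1, NPY1R, CASP8 and ALK are among those left out. Per neuroblastoma line and direction, the 6 genes with the largest gap to the nearer other line were named. A fold is given as "at least" where the dimmer side was under 100 on all its arrays, and is then the geometric mean of the brighter side over 100.

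The 24 gene lists were EWSR1-FLI1 induced and repressed genes, sympathoadrenal transcription factors, catecholamine, cholinergic, neuronal, and granin and neuropeptide genes, mesenchymal, HOX, epithelial, leukocyte, endothelial, and Schwann and glial genes, receptor tyrosine kinases, MHC class I, interferon-response, hypoxia, cancer-testis, 2p24 amplicon, imprinted, proliferation, MYC-responsive, apoptosis and ribosomal protein genes. A list stood apart where its median log2 difference lay outside percentiles 2.5 to 97.5 of 10000 random lists of the same size, matched on mean expression in 20 bins. Genes are not replicates, so such a percentile is a description and not a p-value. Genes were also counted by fixed rules of size with no test, 4-fold for SK-N-MC and 8-fold for a neuroblastoma line. Where a count is adjusted over a list alone, each list was adjusted separately, with no correction across the 24 lists. The groups, lists, rules, main tests and alternatives were chosen before the data were examined. The alternatives of the chromosome comparison and the markers and tests of the closing part were chosen after seeing the data. The adjustment over a list alone, list medians against single lines and the division of chromosomes into equal parts were not in the plan made beforehand.

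On simulated data with the same design, and gene variances drawn from the prior that eBayes fitted, 4 of 9226 unchanged genes were called. Of 50 genes each with a true log2 difference of 2, 3, 4 and 6, 2%, 16%, 50% and 86% were called. In that simulation, most differences of 2 and 3 were thus missed. Of 200 simulated lists of 20 genes, 2.5% stood apart with no shift and 93.5% with a shift of 0.5. The simulated genes varied independently of each other, so these shares need not hold for lists of genes that vary together. Simulated variances did not depend on brightness and simulated values had no lower limit. The shares of called genes need therefore not hold for dim genes, which make up many of the real calls.

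The alternatives tried were quantile normalization, scaling to a common median, pseudocounts of 10 and 150, a floor at 100, no filter on dim probe sets, a filter at 250, the mean of a gene's probe sets, each probe set on its own, eBayes with an intensity trend, robust eBayes, and leaving out each neuroblastoma line. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.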

Results

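Transcript levels were measured in 4 established human cell lines, with 1 array per line. SK-N-MC is a line of the Ewing family of tumors, in most of which a chromosome translocation joins the EWSR1 gene to FLI1 or another ETS-family gene. SIMA, CHP-126 and SH-SY5Y are neuroblastoma lines, derived from a childhood tumor of the sympathetic nervous system. The median deposited signal over 22283 probe sets was 154.9 in SK-N-MC, 155 in SIMA, 165 in CHP-126 and 176.6 in SH-SY5Y. Between 58.5% (SIMA) and 61.4% (SH-SY5Y) of the probe sets had a signal of at least 100, the limit below which a probe set was treated as dim. The ratio of the 3' to the 5' probe set of GAPDH lay between 0.748 (SH-SY5Y) and 0.898 (SIMA), and that of ACTB between 0.879 (SH-SY5Y) and 1.30 (SK-N-MC). Precision was limited by the number of arrays, since each line was measured on 1 array and the spread given for the neuroblastoma group is the spread between 3 different lines (mean ± SD, n = 3).

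The first comparison set the Ewing family line against the neuroblastoma lines. CCK, PENK and GRP, called higher in SK-N-MC, encode neuropeptide precursors. CCK, the precursor of cholecystokinin, had a signal of 8821 in SK-N-MC against 12.1 ± 4.76 in the neuroblastoma lines (SD, n = 3), at least 88.2-fold higher. PENK, the precursor of the enkephalins, had 12361 against 59.8 ± 76.9, and GRP, the precursor of gastrin-releasing peptide, had 6914 against 28.5 ± 32.6, at least 69.1-fold higher. STEAP1, a cell-surface protein gene of the STEAP family, stood at 7731 against 60.2 ± 59.7, and CAV1, the main coat protein of caveolae, at 8514 against 75.2 ± 75.9. NKX2-2, a homeobox transcription factor used as a tissue marker of Ewing sarcoma, stood at 2176 against 18.2 ± 18.3, at least 21.7-fold higher.

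DDC and CHGA were among the genes called lower in SK-N-MC. DDC, the decarboxylase that makes dopamine, had a signal of 5.1 in SK-N-MC against 5533 ± 3948 in the neuroblastoma lines (SD, n = 3), at least 47.4-fold lower. CHGA, which encodes the secretory granule protein chromogranin A, had 29.4 against 6895 ± 3897, at least 62.6-fold lower. CHRNA3, a nicotinic acetylcholine receptor subunit of autonomic ganglia, had 23.4 against 3892 ± 678, at least 38.5-fold lower. The transcription factor gene GATA3 had 207 against 10799 ± 2918, and PHOX2A, a transcription factor gene of noradrenergic neurons, had 88.0 against 3802 ± 812, at least 37.5-fold lower.

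By limma with Benjamini-Hochberg adjustment, 68 of 9426 genes differed between SK-N-MC and the neuroblastoma lines, 41 of them higher and 27 lower in SK-N-MC. All 68 lay beyond all 3 neuroblastoma lines, the smallest difference being 3.22 on the log2(signal + 50) scale, and 1294 genes had an unadjusted p under 0.05. Of the 41 higher genes, 32 were dim in all 3 neuroblastoma lines, and of the 27 lower genes, 19 were dim in SK-N-MC. The lone SK-N-MC array was taken to vary like the neuroblastoma lines, which left 2 residual degrees of freedom. No gene passed by limma at a pseudocount of 10 (lowest adjusted p 0.0722, 1259 genes at an unadjusted p under 0.05), with dim probe sets kept (0.0553, 1521 genes), or without SIMA (0.13, 1135 genes), CHP-126 (0.15, 1078 genes) or SH-SY5Y (0.0636, 1410 genes). The count was 103 at a pseudocount of 150, and 160, with 133 higher, where signals under 100 were set to 100.

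The order of called genes by difference in log2(signal + 50) depends on the pseudocount where a side is dim and is no ranking by fold. The 12 with the highest differences were CCK (adjusted p 0.0335), PENK, GRP, ITM2A, CAV1, STEAP1, PPP1R1A, YBX3, CCND2, CRIP1, ANXA1 and NKX2-2 (adjusted p 0.0348). ITM2A, which encodes a membrane protein, had a signal of 7991 in SK-N-MC and 44.7 ± 43.0 in the neuroblastoma lines (SD, n = 3). CCND2, which encodes cyclin D2, had 5374 against 74.3 ± 72.9, and PPP1R1A, an inhibitor of protein phosphatase 1, had 2949 against 3.9 ± 0.346. YBX3, a cold-shock domain protein gene, had 3201 against 11.5 ± 9.49, and CRIP1 had 3004 against 14.3 ± 5.2. The 12 with the lowest differences were DDC (adjusted p 0.0449), CHGA, CHRNA3, ICA1, TLX2, GATA3, RGS4, TBX2, PHOX2A, NDRG4, FEV and NES (adjusted p 0.0381). RGS4, a regulator of G-protein signalling, had 156 against 6608 ± 2795. NES, which encodes the intermediate filament protein nestin, had 18.7 against 1789 ± 576. FEV, an ETS-family transcription factor gene, had 11.6 against 1609 ± 272, and TLX2, a homeobox gene, had 3.5 against 2534 ± 852.

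**Figure D1:**
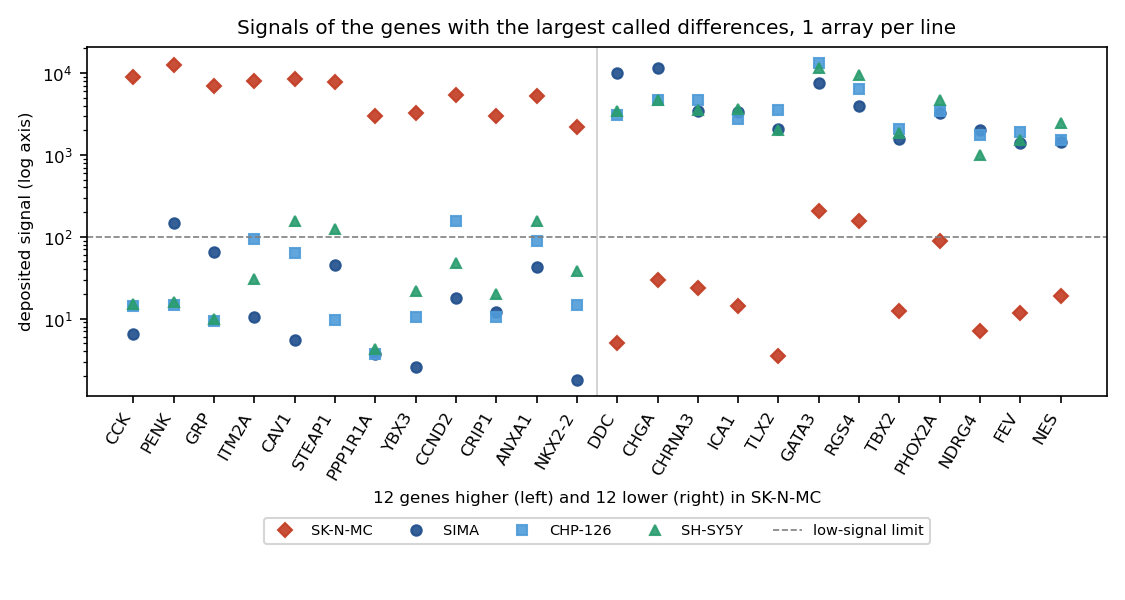
Deposited signal (vertical log axis) of the 12 called genes with the highest and the 12 with the lowest log2 difference, with a point for each of the 4 lines and a dashed line at the low-signal limit of 100. In the first set SK-N-MC lies above all 3 neuroblastoma lines (CCK 8821 against 12.1 ± 4.76, SD, n = 3), and in the second below them (DDC 5.1 against 5533 ± 3948).

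Groups of genes chosen before the data were examined were set against 10000 random lists of the same size and brightness, as a description of these arrays. The EWSR1-FLI1 induced genes, reported in the literature to rise with the fusion protein of Ewing tumors, had a median log2 difference of 2.88 in SK-N-MC, at percentile 100 of the random lists. Of 26 measured members, 5 were called higher (CAV1, STEAP1, PPP1R1A, NKX2-2 and IL1RAP, the last named after its values were seen), 0 lower, and 21 did not pass. The count adjusted over the list alone was 15 higher and 0 lower. Such lists were drawn up in part on Ewing tumor lines, which can include SK-N-MC, so they are not independent evidence of the direction. FLI1, the gene of the ETS partner, had a signal of 676 in SK-N-MC against 44.1 ± 7.51 in the neuroblastoma lines (SD, n = 3; adjusted p 0.0532), and CD99, a surface antigen used to diagnose Ewing tumors, 7407 against 1658 ± 1414 (adjusted p 0.527). The EWSR1-FLI1 repressed genes had a median of -0.81 (percentile 0.53), with 0 of 12 called in either direction and 1 lower when adjusted over the list alone. That median differed by line, being 0.34 against SIMA, -0.16 against CHP-126 and -1.55 against SH-SY5Y. CDKN1A stood at 36.4 against 757 ± 355 and DKK1 at 27.7 against 1385 ± 1221, while LOX stood at 894 against 178 ± 174. That median lay inside the range of the random lists without SH-SY5Y (-0.18, percentile 29.3) and with signals under 100 set to 100 (-0.56, percentile 3.31).

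The sympathoadrenal transcription factors, which specify the lineage of sympathetic neurons and chromaffin cells, had a median of -3.0, at percentile 0. Of 14 measured members, 0 were called higher, 3 lower (GATA3, TBX2 and PHOX2A), and 11 did not pass. There were 8 lower and 0 higher when adjusted over the list alone. HAND1 had a signal of 212 in SK-N-MC against 4636 ± 2469 (SD, n = 3) and HAND2 12.5 against 361 ± 74.6. The neuronal cytoskeleton and synapse genes had a median of -2.14 (percentile 0). Of 26, 1 was called lower (RTN1, -3.69, named after its values were seen), 0 higher, and 25 did not pass, and 11 were lower and 0 higher when adjusted over the list alone. The axon growth protein gene STMN2 had 37.7 against 5617 ± 3829 (adjusted p 0.0821), and the neurofilament genes NEFM and NEFL had 9.3 against 4302 ± 5546 and 18.0 against 2801 ± 2523. ELAVL4, which encodes a neuronal RNA-binding protein, had 185 against 4267 ± 1630 (adjusted p 0.0675).

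The genes of catecholamine synthesis and transport had a median of -2.04 (percentile 0), with DDC called lower among 14 measured members, 0 called higher and 13 not passing. Adjusted over the list alone, 1 was lower and 0 higher. DBH, which converts dopamine to noradrenaline, had 47.5 in SK-N-MC against 1566 ± 1910 in the neuroblastoma lines (SD, n = 3; adjusted p 0.484), and TH, the rate-limiting enzyme of the pathway, had 10.8 against 449 ± 476 (adjusted p 0.613). The cholinergic genes had a median of -0.83 (percentile 0.48), with CHRNA3 called lower among 10, 0 called higher and 2 lower when adjusted over the list alone. Without SH-SY5Y that median was -0.58 (percentile 3.03), and with signals under 100 set to 100 it was -0.37. The granins, peptide processing genes and neuropeptides had a median of -1.51 (percentile 0), and their called members ran both ways. Of 19, 3 were called higher (CCK, PENK and GRP), 1 lower (CHGA) and 15 did not pass, and 3 were higher and 5 lower when adjusted over the list alone.

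The mesenchymal and matrix genes had a median of 1.66 (percentile 100), which differed by line, being 2.88 against SIMA, 1.83 against CHP-126 and -0.27 against SH-SY5Y. It was 0.81 without SIMA and 2.67 without SH-SY5Y. Of 30, 1 was called higher (ANXA1, signal 5284 against 96.1 ± 57.7, SD, n = 3), 0 lower, and 29 did not pass. Adjusted over the list alone, 3 were higher and 1 lower. COL1A2, a chain of type I collagen, had 7415 against 67.3 ± 93.8 (adjusted p 0.0548), whereas VIM had 4784 against 13859 ± 8004. The HOX genes, which pattern the body axis, had a median of 1.07 (percentile 99.99), with HOXB13 called higher among 18, 0 lower and 17 not passing, and 7 higher and 0 lower when adjusted over the list alone. HOXD13 had 607 against 26.6 ± 34.6, and HOXC11 had 892 against 86.3 ± 59.6. Of the 39 HOX genes in the list, 18 passed the filter on dim probe sets, and the median was 0.39 over 24 genes with dim probe sets kept, 2.67 over 11 genes with the filter at 250, and 0.60 without CHP-126. The receptor tyrosine kinases and co-receptors had a median of 0.35 (percentile 98.1), with FGFR3 (1571 against 15.2 ± 3.09) and EPHA4 (823 against 6.77 ± 1.46) called higher among 25, 0 lower and 23 not passing. Adjusted over the list alone, 3 were higher and 1 lower. In 6 other settings, quantile normalization (0.27) and signals under 100 set to 100 (0.18) among them, that median lay inside the range of the random lists. Over all other settings it ran from 0.16 to 0.68. Against single lines the receptor median was 0.61 (SIMA), 0.73 (CHP-126) and 0.005 (SH-SY5Y).

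Markers of other cell types were also measured. Of 6 epithelial genes (median 2.50, percentile 99.99), KRT8 (2220 against 68.5 ± 29.4, SD, n = 3) and DSP (1008 against 48.1 ± 13.5) were called higher, 0 lower, and 4 did not pass, with 4 higher and 0 lower when adjusted over the list alone. KRT18 had 6024 against 426 ± 469 (adjusted p 0.177), and 8 of 10 other epithelial markers, CDH1 and KRT19 among them, were dim in SK-N-MC. The list held 14 genes, of which 6 passed the filter that brightness in SK-N-MC helps to decide, and over all 14, dim ones kept, the median was 0.49 (percentile 99.6). Of 7 leukocyte genes (median 0.85, percentile 98.6), PTPRC was called higher (1368 against 37.6 ± 11.7), 0 lower, and 6 did not pass, with 2 higher and 0 lower when adjusted over the list alone. LCP1 had 1069 against 65.7 ± 48.5 (adjusted p 0.0869). Without CHP-126 the leukocyte median was 0.76 and inside the range of the random lists (percentile 97.05), and with dim probe sets kept it was 0.46 over 13 genes. Endothelial genes (median 0.15, 7 genes) and Schwann and glial genes (median -0.35, 5 genes) did not stand apart, with 0 called in either list. Adjusted over the list alone, 0 endothelial genes passed and 1 Schwann and glial gene was higher, NGFR, with 636 against 24.6 ± 22.6. Its limma adjusted p over all genes was 0.0738.

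The genes of MHC class I presentation had a median of 0.84 (percentile 99.98), with 0 of 13 called, also when adjusted over the list alone. HLA-C had 3272 in SK-N-MC, 139.5 in SIMA, 193 in CHP-126 and 2292 in SH-SY5Y. The interferon-response genes had a median of 0.60 (percentile 98.8), with IFITM1 called higher among 16 (1350 against 92.2 ± 12.1, SD, n = 3), 0 lower and 15 not passing, and 2 higher and 0 lower when adjusted over the list alone. That median lay inside the range of the random lists in 4 settings, at 0.48 without SIMA, 0.32 without CHP-126, 0.34 with dim probe sets kept and 0.23 with signals under 100 set to 100. It was 2.19 over 7 genes with the filter at 250. The hypoxia and glycolysis genes had a median of 0.40 (percentile 99.4), with 0 of 21 called, also when adjusted over the list alone. BNIP3L had 3477 against 1303 ± 231, while HK1 had 238 against 1673 ± 693. Without SH-SY5Y their percentile was 97.4. The cancer-testis antigens had a median of -1.14 (percentile 0.16) and the 2p24 amplicon genes, neighbours of MYCN, one of -0.68 (percentile 0.71), with 0 of 7 and 0 of 8 called, also when adjusted over each list alone. MAGEA6 had 7.0 in SK-N-MC and 8.0, 740 and 2443 in SIMA, CHP-126 and SH-SY5Y. Against single lines the cancer-testis median was 0.10 (SIMA), -0.53 (CHP-126) and -1.60 (SH-SY5Y), and the 2p24 median -1.04, -0.63 and 0.02. The cancer-testis median was -0.31 without SH-SY5Y (percentile 21.0) and -0.02 over 18 genes with dim probe sets kept (percentile 49.3). That of the 2p24 amplicon genes was -0.26 without SIMA (percentile 15.4) and -0.28 with dim probe sets kept (percentile 7.83).

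The other 5 lists lay inside the range of the random lists with the settings used throughout, but the imprinted genes stood apart in 6 of 11 other settings. The median was 0.18 for 27 proliferation genes, 0.16 for 20 MYC-responsive nucleolar and growth genes, 0.14 for 20 apoptosis regulators, 0.02 for 25 cytosolic ribosomal protein genes and -0.48 for 13 imprinted genes. None of their members was called. Adjusted over the list alone, 1 imprinted gene was higher (GRB10, 765 against 70.9 ± 21.1, SD, n = 3) and 1 lower (PEG3, 115 against 834 ± 216), and 0 passed in the others. Over all genes, the limma adjusted p was 0.075 for GRB10 and 0.109 for PEG3. The imprinted median was -0.94 without SH-SY5Y, -0.58 without CHP-126, -0.52 under quantile normalization (percentile 2.03), -0.47 at a pseudocount of 150, -0.78 with the filter at 250 and -0.57 with the mean of probe sets, and -0.16 without SIMA (percentile 31.9). The proliferation median was 0.40 without SIMA (percentile 98.6) and 0.31 without SH-SY5Y (percentile 98.4). With signals under 100 set to 100, which bounds differences of dim genes, medians were 2.89 for the EWSR1-FLI1 induced genes, 2.25 for the epithelial, 1.31 for the mesenchymal, -2.50 for the sympathoadrenal, -2.06 for the neuronal and -1.59 for the catecholamine list.

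**Figure D2:**
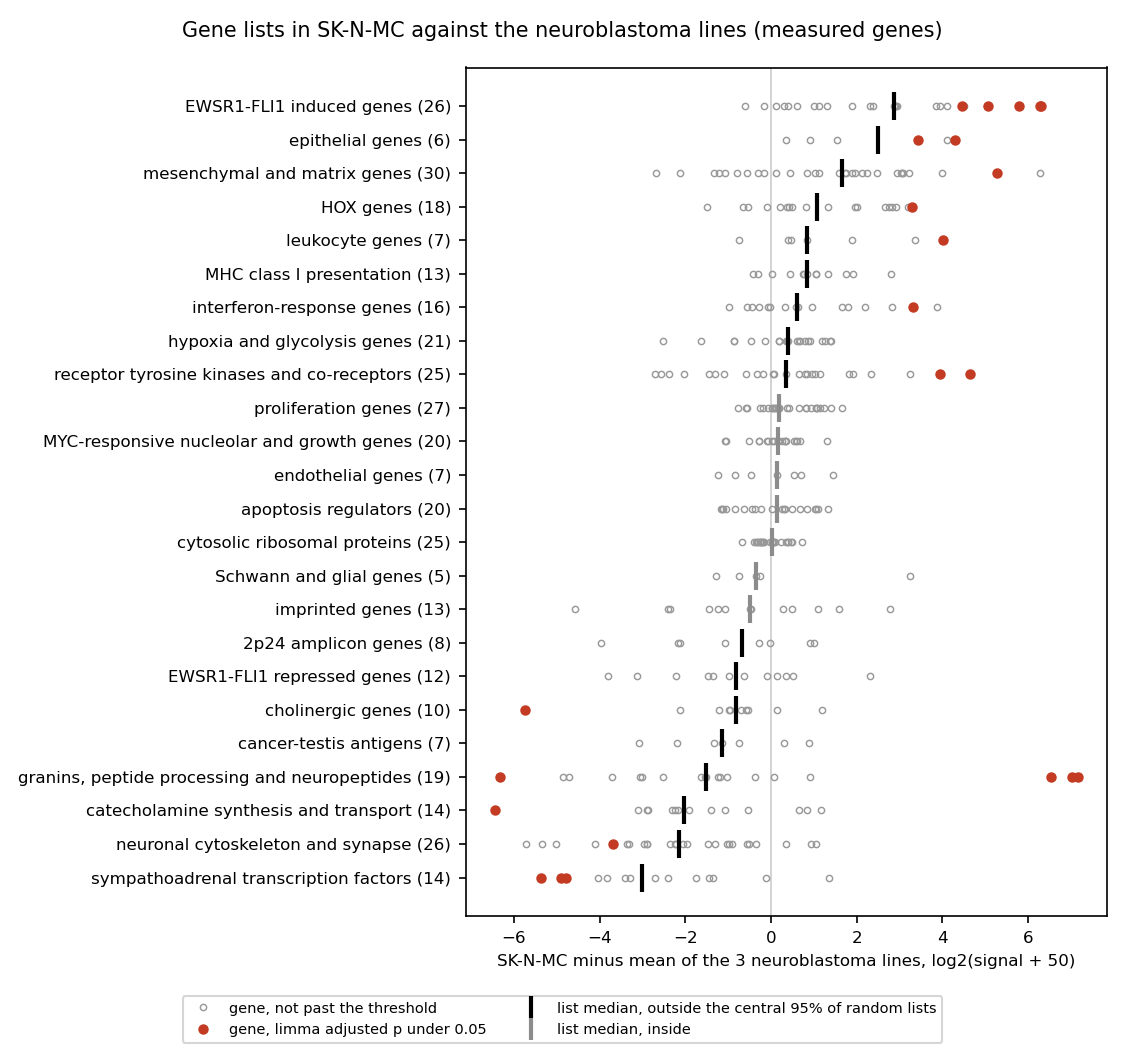
Log2 difference between SK-N-MC and the mean of the 3 neuroblastoma lines (horizontal axis, log2 of signal + 50) for each measured gene of the 24 lists, with list medians as bars. Filled points are genes called by limma. Medians run from -3.0 for the sympathoadrenal transcription factors to 2.88 for the EWSR1-FLI1 induced genes, and bars are black where the median lay outside the central 95% of random lists.

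By correlation across genes, SK-N-MC stood further from the other lines than any neuroblastoma line did. In it, 159 genes were at least 4-fold above and 169 at least 4-fold below every neuroblastoma line. With each neuroblastoma line in its place, the same rule gave 31 and 27 genes for SIMA, 34 and 28 for CHP-126, and 37 and 3 for SH-SY5Y. A neuroblastoma line had to lie beyond SK-N-MC too, so a gene at a like level in SK-N-MC could not count. These counts are therefore no fair comparison for those of SK-N-MC. SK-N-MC had the highest signal of the 4 lines for 29.2% of the genes and the lowest for 32.3%, where chance gives 25% each. SH-SY5Y was highest for 27.4% and lowest for 22.7%. Across genes, the Pearson correlation of log2 values was 0.767 between SK-N-MC and SIMA, 0.752 with CHP-126 and 0.772 with SH-SY5Y. It was 0.884 between SIMA and CHP-126, 0.863 between SIMA and SH-SY5Y, and 0.856 between CHP-126 and SH-SY5Y. Spearman's rho ran from 0.727 to 0.754 for the pairs with SK-N-MC and from 0.844 to 0.874 within the neuroblastoma lines. Genes are not independent replicates, so these 6 pairs carry no p-value.

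The neuroblastoma lines were then compared with each other, with 1 array per line and no test. MYCN, the proto-oncogene amplified in many neuroblastomas, had a signal of 5390 in SIMA, 9654 in CHP-126 and 96.7 in SH-SY5Y, against 77 in SK-N-MC. DDX1, its neighbour on chromosome 2, had 24721, 43620 and 3613 in the same order. MYC had 1834 in SH-SY5Y and 5560 in SK-N-MC, and was dim in SIMA (1.5) and CHP-126 (69.1). SST, the precursor of the neuropeptide somatostatin, had 19574 in SIMA, 330 in CHP-126 and 15.4 in SH-SY5Y.

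SIMA had 13 genes at least 8-fold above and 20 at least 8-fold below both other neuroblastoma lines. The largest gaps above in log2(signal + 50), an order that likewise depends on the pseudocount, were those of SST, AMIGO2 (signal 2451 in SIMA, 18.4 in CHP-126 and 36.1 in SH-SY5Y), IER3, ST18, GFRA3, a neurotrophic factor co-receptor (1287, 12 and 26.4), and KCNS3, a potassium channel subunit gene. The largest gaps below were those of KCTD12 (8.2, 4820 and 3140), DDAH1, IGFBP5 (174.8, 11705 and 5734), COL3A1, RGS5 and CLU. CHP-126 had 13 genes above and 18 below. DHRS2 had 7969 in CHP-126, 72.9 in SIMA and 39.7 in SH-SY5Y, followed by FGF13, the neuroendocrine transcription factor gene INSM1 (1442 against 30.6 and 8.8), CRH, the precursor of corticotropin-releasing hormone (3202.5 against 130.5 and 8.2), TNNT1 and TMEM255A. PRKCA (9 in CHP-126, 1085 in SIMA and 2025 in SH-SY5Y), LAMP5, FABP5, NEK9, SCG5 and GPX7 lay furthest below. SH-SY5Y had 36 genes above and 9 below. Its largest gaps above were those of the type IV collagen gene COL4A2 (2162 in SH-SY5Y, 12.2 in SIMA and 21.5 in CHP-126), TAGLN, IGFBP3, C7, NPTX2 and ANXA2, and those below were of MYCN, the imprinted noncoding gene MEG3 (5.3, 3795 and 1764), NRIP1, ENPP2, CXCL12 and LOXL1.

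SH-SY5Y was highest of the 3 lines in 26 of 30 mesenchymal and matrix genes, whose median log2 difference to the mean of the other lines was 2.14 (percentile 100). That median was -1.27 in SIMA and -0.82 in CHP-126. At a pseudocount of 150 the medians were 1.40, -0.68 and -0.51 in SH-SY5Y, SIMA and CHP-126, and with signals under 100 set to 100 they were -0.72 in SIMA and -0.51 in CHP-126, all still apart from the random lists. TAGLN, an actin-binding protein gene, had a signal of 3265 in SH-SY5Y, 58.6 in SIMA and 5.2 in CHP-126, and ANXA2, which encodes annexin A2, had 7779, 126 and 310. SH-SY5Y was lowest in 18 of 26 neuronal cytoskeleton and synapse genes, with a median of -1.11 (percentile 0), and in 6 of 8 genes of the 2p24 amplicon list (-1.39). The neuronal median was 0.50 in SIMA and 0.58 in CHP-126. Proliferation genes had a median of -0.34 in SH-SY5Y and 0.40 in SIMA, and the genes of MHC class I presentation 0.57 in SH-SY5Y and -0.57 in CHP-126 (-0.33 at a pseudocount of 150 and -0.37 with signals under 100 set to 100).

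Granins, peptide processing genes and neuropeptides were highest in SIMA for 14 of 19 members, with a median of 0.90 (percentile 100), against -0.26 in CHP-126 (-0.15 with signals under 100 set to 100) and -0.53 in SH-SY5Y. Genes of catecholamine synthesis and transport had a median of 0.67 in SIMA and -0.80 in CHP-126, and SH-SY5Y, at 0.02, lay inside the range of the random lists. SH-SY5Y had a TH signal of 3.4 beside 3406 for DDC and 3733 for DBH. In SIMA, TH stood at 951 and DBH at 128. The sympathoadrenal transcription factors had a median of -0.47 in SIMA (percentile 0.02). In all, 11 of the 24 lists stood apart in SIMA, 7 in CHP-126 and 10 in SH-SY5Y, against 17 in SK-N-MC, so that standing apart from random lists was common in any single line. Signals under 100 set to 100, or dim probe sets kept, returned the cancer-testis lists of SIMA and SH-SY5Y and the Schwann and glial list of CHP-126 to the range of the random lists. So did signals under 100 set to 100 for the Schwann and glial list (-0.18) and the granin list (-0.24) of SH-SY5Y and the EWSR1-FLI1 induced (-0.08) and interferon-response (-0.22) lists of SIMA. The mean of probe sets did so for the Schwann and glial list of SH-SY5Y (-0.22), a pseudocount of 150 for the EWSR1-FLI1 induced list of SIMA (-0.22), the filter at 250 for its interferon-response list (-0.62), and quantile normalization for its ribosomal protein list (-0.05). Other lists stood apart only in some of the other settings, namely the interferon-response genes of SH-SY5Y in 5, the cholinergic genes and the sympathoadrenal transcription factors of CHP-126 in 3 each, the sympathoadrenal transcription factors of SH-SY5Y in 2, and the imprinted genes of CHP-126 and the EWSR1-FLI1 repressed genes of SIMA in 1 each.

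**Figure D3:**
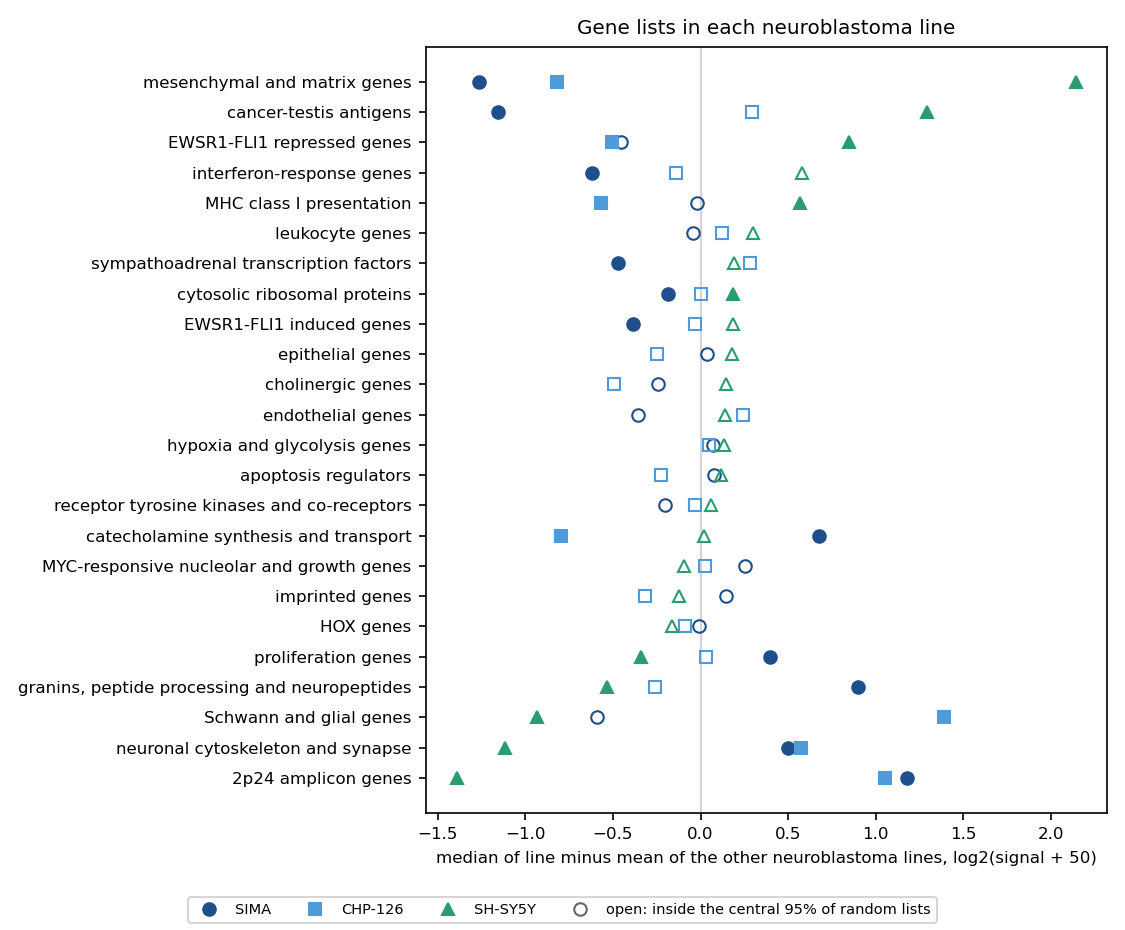
Median log2 difference (horizontal axis, log2 of signal + 50) of each of the 24 gene lists between a neuroblastoma line and the mean of the other 2 lines, with filled points outside the central 95% of random lists. The mesenchymal and matrix genes run from -1.27 in SIMA to 2.14 in SH-SY5Y, and the 2p24 amplicon genes from -1.39 in SH-SY5Y to 1.18 in SIMA.

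Expression was also compared by chromosome, each line against the mean of the other 3, as an exploratory comparison with gene order taken from the GRCh38.p14 annotation. SK-N-MC had a median of 0.49 on chromosome 8 over 361 genes, -0.40 on chromosome 10, -0.40 on chromosome 16 and -0.31 on chromosome 17. The chromosome 8 median was 0.46 against SIMA, 0.53 against CHP-126 and 0.56 against SH-SY5Y. In 4 equal parts of the gene order, it was 0.06 in the first and between 0.47 and 0.85 in the other 3. On chromosome 16 the 4 parts stood at -0.15, -0.19, -0.71 and -0.61. SH-SY5Y had a median of 0.37 on chromosome 7 and 0.22 on chromosome 1, and CHP-126 one of 0.29 on chromosome 2. On chromosomes 8, 16 and 18 SH-SY5Y had -0.26, 0.23 and -0.23, and on chromosome 10 SIMA had 0.24. In the first 240 genes of chromosome 1, CHP-126 had a median of -0.51 and SIMA one of -0.37, against 0.47 in SH-SY5Y and 0.41 in SK-N-MC. For each gene the differences of the 4 lines cancel out, so low values in some lines force high values in others. The parts of chromosomes given here were picked from those of all chromosomes. Over the 4 lines and chromosomes 1 to 22 and X, 49 combinations of line and chromosome lay outside the central 95% of random lists. Lying outside was thus common and does not set the chromosomes named here apart.

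**Figure D4:**
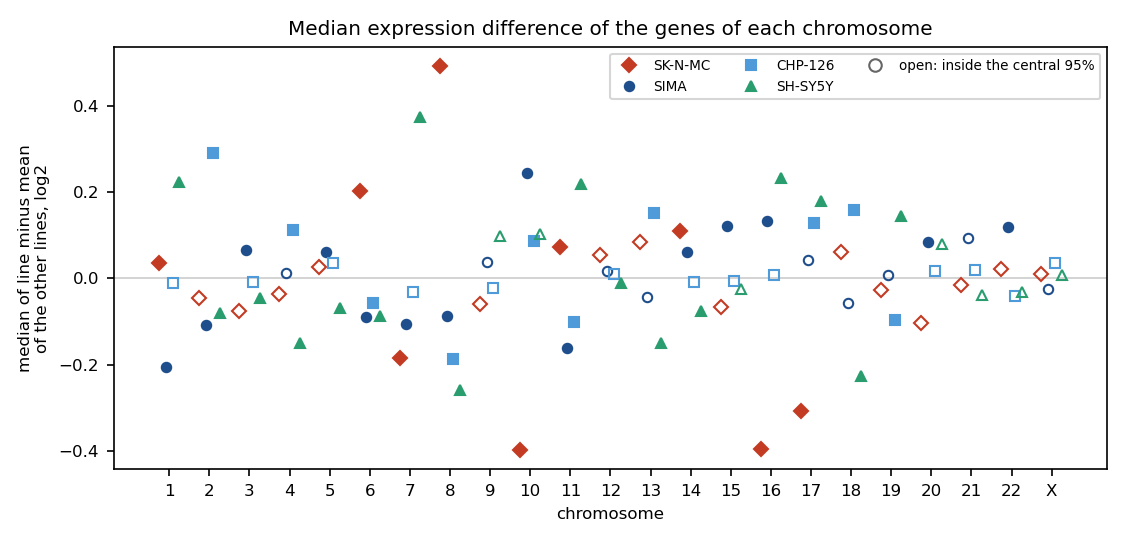
Median log2 difference (vertical axis) of the genes of each chromosome between a line and the mean of the other 3 lines, with filled points outside the central 95% of random lists. The largest value is that of chromosome 8 in SK-N-MC (0.49), and the lowest are those of chromosomes 10 and 16 in SK-N-MC (-0.40 each).

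Near the start of chromosome 2, SIMA was brighter than both other neuroblastoma lines in separate stretches on either side of MYCN. ODC1, which encodes ornithine decarboxylase, had a signal of 40310 in SIMA, 9021 in CHP-126 and 7368 in SH-SY5Y. ROCK2 had 3467, 652 and 417 in the same order, E2F6 had 2043, 710 and 412, SMC6 had 5031, 1222 and 1202, and KCNS3 had 2961, 157 and 69.2. Of the first 44 measured genes of the chromosome, 8 were at least 2-fold above both other lines in SIMA, namely HPCAL1, ODC1, ROCK2, E2F6, CYRIA, VSNL1, SMC6 and KCNS3. PDIA6, between ODC1 and ROCK2, had 3693 in SIMA, 4161 in CHP-126 and 4820 in SH-SY5Y, and GREB1, on the other side of E2F6, had 103, 454.5 and 355. These genes were chosen after their values were seen, except KCNS3 and the members of fixed lists.

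**Figure D5:**
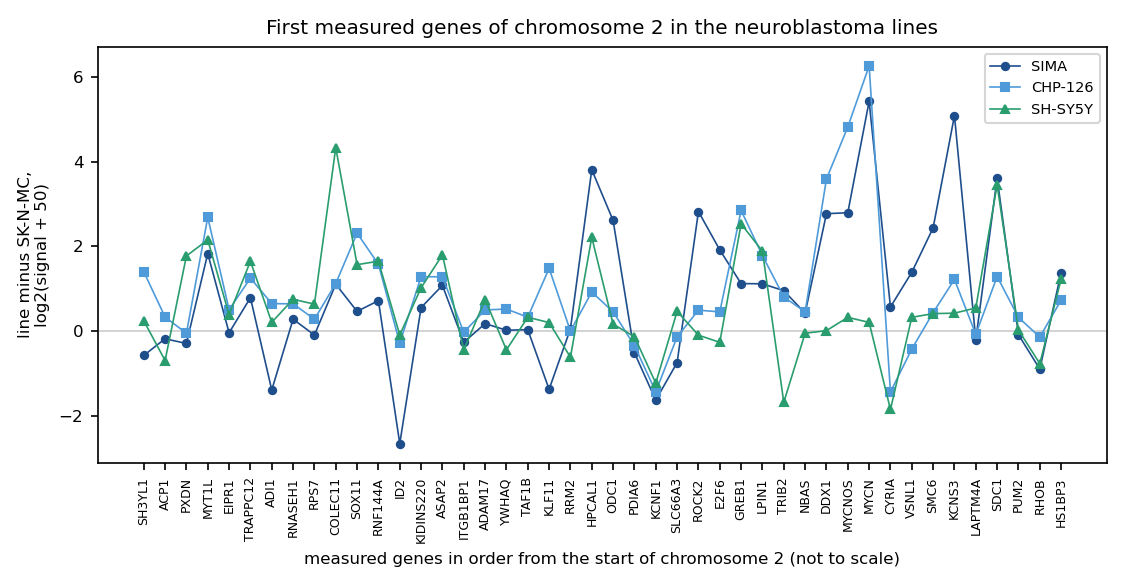
Log2 difference (vertical axis, log2 of signal + 50) between each neuroblastoma line and SK-N-MC for the first 44 measured genes of chromosome 2, in gene order and not to scale. MYCN and DDX1 stand high in SIMA and CHP-126, and ODC1, ROCK2, SMC6 and KCNS3 in SIMA.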

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

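The tests of technical explanations in this part were chosen only after the results they concern had been seen. Signals were also present in probe sets that the comparisons did not use. Of 2015 probe sets with no gene symbol or with several, 10 were at least 4-fold above all 3 neuroblastoma lines in SK-N-MC and 22 at least 4-fold below them, and no gene is named for them. The middle probe set for 28S ribosomal RNA, a control, had a signal of 581.9 in SK-N-MC, 486.2 in SIMA, 214.4 in CHP-126 and 154.3 in SH-SY5Y. No group held enough samples for a test of outlying arrays.

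With each line in turn placed alone against the other 3, only SK-N-MC gave genes called by limma, 68, against a highest count of 0 for the others (251, 312 and 368 genes at an unadjusted p under 0.05). With a neuroblastoma line alone, the spread was estimated from 3 lines that included SK-N-MC. That widens the spread of genes in which SK-N-MC lies apart, so the counts of 0 are no fair comparison for the 68. SK-N-MC was also 1 of 4 possible choices, too few for a share under 0.05.

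PTPRC, LCP1, KRT8, KRT18 and DSP were bright in SK-N-MC, and cells of other types in the culture may be a candidate explanation. Of 14 other leukocyte markers, 2 were above the low-signal limit and above all neuroblastoma lines (CD53 at 243.7 and ITGB2 at 101.3). A further 11 were dim, LYZ (57.6), CD74 (16) and SRGN (4.2) among them. Of these 11, LYZ, CD14, LAPTM5 and TYROBP still stood highest in SK-N-MC, and the rest did not. LYZ had 2.1 in SIMA, 2.5 in CHP-126 and 2.0 in SH-SY5Y. Of 10 other epithelial markers, 1 was above the limit and above all neuroblastoma lines (EPCAM at 101.9). A further 8 were dim, with CDH1 at 45.3 and KRT19 at 2.1. Of these 8, CDH1, CLDN7 and ESRP1 still stood highest in SK-N-MC, and the rest did not. Such levels speak against a large share of leukocytes or epithelial cells but leave a small share open. Expression of PTPRC, LCP1, KRT8, KRT18 and DSP by SK-N-MC itself was not tested.

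Genes near the start of chromosome 2 were bright in SIMA on either side of MYCN, and amplified stretches of DNA may be a candidate explanation. In 6 of 1000 shuffled gene orders, some window of 25 neighbours held as many genes at least 4-fold above both other neuroblastoma lines as the 4 found between ASAP2 and KCNS3. Among these 4, CYRIA passed narrowly (log2 gap 2.003), with a signal of 510.6 in SIMA and 327.1 in SK-N-MC. SMC6, in the same window, missed narrowly (log2 gap 1.998), so the count of 4 depends on where the limit is set. Faulty probe sets were a poor explanation for HPCAL1, ROCK2 and CYRIA, since 100% of their 3 other probe sets also showed SIMA at least 2-fold higher. The other 5 genes had no other probe set past the filter on dim signals, so the same check was not made for them. Copy number was not analysed here.

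Chromosome 8 genes stood higher in SK-N-MC, and a gain of that chromosome may be a candidate explanation that these data cannot test. Under quantile normalization the median was 0.548, at percentile 100 of random lists matched on brightness, whose own median was 0.01. On the values as deposited it already lay at percentile 100 when chromosome 8 was picked. The outcome was thus largely fixed in advance. It shows only that random genes of like brightness did not share the shift, and decides nothing further about scaling. The test under quantile normalization replaced an earlier version, after the outcome of that version was seen. The earlier version took the lowest of several medians and was undecided. With the genes in 3 equal parts by brightness, the median was 0.15 in the dimmest, 0.63 in the middle and 0.67 in the brightest. The share of genes higher in SK-N-MC was 22.3 percentage points above that of other genes (70.1% against 47.8%), which largely restates the positive median and tests nothing further.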

How the results depend on the processing

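Only the alternatives for chromosomes were chosen after the results were seen. No paired analysis was possible because the 4 arrays are of 4 different cell lines and the labels give no pairing between them. Against 68 genes called by limma (41 higher, 27 lower), 0 were called (0 higher, 0 lower) at a pseudocount of 10 and with dim probe sets kept, with 1259 and 1521 genes at an unadjusted p under 0.05. Leaving out any neuroblastoma line also left 0 (1135, 1078 and 1410 genes without SIMA, CHP-126 and SH-SY5Y), where 1 residual degree of freedom remains. The count was 103 (65 higher) at a pseudocount of 150 and 160 (133 higher) with a floor at 100, and an intensity trend gave 52 lower genes. It was 66 to 98 under quantile normalization, median scaling, the stricter filter, the mean of probe sets, each probe set on its own, the trend and robust eBayes. All 68 genes kept their sign and an unadjusted p under 0.05 in the gene-level alternatives, though 51 of them were called with the floor. Genes at least 4-fold beyond every neuroblastoma line numbered 533 at a pseudocount of 10 and 175 at 150, against 328. Line-specific genes above and below numbered 30 and 49 for SIMA, 30 and 42 for CHP-126 and 80 and 22 for SH-SY5Y at a pseudocount of 10, and 8 and 8, 6 and 2, and 13 and 4 at 150. With the mean of probe sets, 12 genes lay below in SIMA, against 20. A pseudocount compresses differences of dim genes by construction, and the cause of the other changes was not tested. Scaling to a common median moved the median of all genes from -0.03 to 0.09 in SIMA and from 0.04 to -0.09 in SH-SY5Y. In these alternatives no list median that stood apart reversed, and none of the 24 genes named for the highest and lowest called differences changed sign. Of these 24, 9 lost their call with the floor at 100 (adjusted p up to 0.156) and 3 with the mean of probe sets (up to 0.112), beside the settings that left 0 calls. Signs of the other genes named were not tabulated. Signals near the limit of 100 set the precision for dim genes.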
